A study of Drosophila melanogaster with 4 samples.

How the data were processed

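Chromatin accessibility was measured by FAIRE-seq (formaldehyde-assisted isolation of regulatory elements, in which crosslinked, sheared chromatin is extracted with phenol and the nucleosome-depleted DNA left in the aqueous phase is sequenced) in wings of female Drosophila melanogaster pupae. The 4 libraries fell into 2 genotypes of 2 libraries each, and per the labels' protocols each library came from 40 wings. Both genotypes were homozygous for osa-GFP, a tagged allele of osa, which encodes the ARID subunit of the Brahma SWI/SNF nucleosome remodeler. Both also carried UAS-Nslmb-vhhGFP, the deGrad transgene, which encodes an F-box fragment of Slmb fused to an anti-GFP nanobody and directs GFP-tagged proteins to degradation. Only the Osa-deGrad genotype carried the wing driver nub-GAL4, so the control genotype held the transgene without its driver. Per the labels' protocols, animals were raised at 23 °C and moved to 29 °C as wandering larvae, prepupae of 0 to 12 h after puparium formation (APF) were staged, and wings were dissected 24 h later, at 24 to 36 h APF. The labels do not say that the replicates came from separate crosses or days, so any spread between the 2 libraries of a genotype may be technical. The series' design text describes an anti-GFP CUT&RUN assay on larval discs, which differs from the sample labels and the series title; the samples were taken as FAIRE-seq libraries of pupal wings.

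The deposited files were 1 peak list per library in narrowPeak format on dm6, so peaks were called on each library and not on pooled replicates. The submitters' processing notes name Bowtie2 2.3.4.1, SAMtools 1.9, Picard 2.2.4, deepTools 2.4.1 and MACS2 2.1.2 without giving roles, and the peak names in the files mention trimming, a q5 filter, sorting and duplicate removal. The peak caller's settings and any control track are not given in the sources used here. Each peak in the authors' lists carries a fold enrichment at the summit (a ratio over the caller's local background), −log10 p and −log10 q values, and an integer score that equalled the integer part of 10 times the −log10 q value for every peak of the deposited files. The deposited files also give the summit as an offset from the peak start, from which summit positions were computed. Coordinates are given 1-based. The lowest −log10 q value in the authors' deposited lists lay between 1.31 and 1.40 per library. Read counts and library depths are unknown from these files. The number of peaks and the −log10 q values rise with depth, and a peak absent from a list can be a site just under the caller's threshold. The authors' fold and −log10 q values were therefore used to describe, rank or filter peaks within their own list. Where such values or percentile ranks of several libraries are given together, each describes the peak within its own list and no difference between libraries was tested on them. In the closing observations, regions present in all 4 lists were re-ranked among themselves and those ranks were compared. Beyond that, no value was compared between libraries as a signal, and no interval or floor that needs read counts was given.

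Peaks of the 4 lists were merged into regions when they overlapped by at least 1 bp. A region was called deGrad-only when both Osa-deGrad lists and neither control list held a peak there, and control-only in the reverse case. The same count was made for the other 2 ways to split 4 libraries into pairs. With 3 splits the smallest exact p for any per-library comparison is 0.333, so no such p is printed. Fisher's exact tests (two-sided) and permutation tests (100000 resamples, two-sided, smallest p 1e-05) compared classes of regions. Regions are not replicates, so these tests describe the 4 libraries and do not generalise to the genotypes. Shares of regions carry 95% Wilson intervals, which cover counting error only. Gene positions came from the RefSeq gene table of Release 6 plus ISO1 MT, the assembly that dm6 names. The table gives gene starts and ends without strand or exons, so the planned distance to a transcription start site was replaced by the distance from the summit to the nearest end of any annotated gene, with 500 bp as the window for "near a gene end". Start sites inside a gene were thus missed, and 3′ ends were counted. Each region was assigned to the protein-coding gene with the nearest end. The planned comparisons of GC content and sequence motifs were not run, since no genome sequence was used here.

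The tests, the alternatives, the rule for named genes and the gene lists were fixed before the data were examined. The lists held 13 groups: ecdysone response, wing selector and patterning factors, signalling pathway genes, sensory organ development, cuticle, hair and wing differentiation, SWI/SNF subunits, markers of hemocytes, muscle, neurons and glia, trachea and fat body, transgene vector sequences, and cytoplasmic ribosomal protein genes. All written symbols matched the gene table directly or through a synonym, with 2 symbols of the SWI/SNF list naming the same gene. For each list, the share of regions specific to either genotype was compared with that of all other regions present in at least 2 lists, with Benjamini-Hochberg adjustment over the 13 lists. Odds ratios of the gene lists have 0.5 added to every cell. The named genes were fixed by rule: the 12 regions per direction with the highest percentile rank by −log10 q in the weaker of their 2 lists, up to 4 genes per list and direction by the same rank, and osa, br, nub, w and the Hsp70 genes in every case. In this ranking 100 is the strongest peak of a list.

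Alternatives were −log10 q minima of 5 and 10, presence only above the percentile rank of 50 of a list (absence judged on the full lists), lists cut to the shortest list (13953 peaks), matching by summits within 100 bp or by an overlap of at least 50% of the shorter peak, main chromosome arms only, each library left out, lists cut to equal length within each replicate number, a 1000 bp window, assignment by gene body with a 5 kb flank, and a background of regions in exactly 2 lists. Tests of each direction alone for the gene lists, comparisons of 1 library against 1, counts by location, and shares off chromosome 2 were added after seeing the data. What the shares off chromosome 2 would show was written down before that value was computed. The region calls were also run on 24067 simulated regions with 200 specific regions per direction. Under each matching rule 200 deGrad-only and 200 control-only regions were recovered, with 0 crossed calls. The deposited lists held 801 crossed calls, so the simulated lists lacked the scatter of peaks between libraries seen there. The simulation therefore checked only how the calling rules were applied. It cannot show how many genotype-specific calls are false. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.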

Results

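FAIRE-seq peak lists were compared between pupal wings in which Osa-GFP was targeted for degradation by nub-GAL4 and deGrad (Osa-deGrad, 2 libraries) and wings with the deGrad transgene but no driver (control, 2 libraries). The Osa-deGrad lists held 13959 peaks in replicate 1 and 17048 in replicate 2, and the control lists 13953 and 18007. Peaks covered 3847 and 5183 kb in the Osa-deGrad libraries and 3805 and 5535 kb in the controls. The median peak width was 217 to 244 bp, and the authors' median fold enrichment was 4.58 to 5.25. Both replicate 2 lists were longer than both replicate 1 lists, with a median −log10 q of 10.6 and 10.1 against 7.004 and 6.65, so list length followed the replicate number and not the genotype. The number of peaks did not separate the genotypes, at 15504 ± 2184 (SD, n = 2) in Osa-deGrad and 15980.0 ± 2867 (SD, n = 2) in control wings.

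The first comparison asked whether wings with targeted Osa kept the same set of open regions. Most reproducible regions were found in both genotypes. Of 24088 merged regions, 15813 were present in at least 2 lists and 7900 in all 4. Of the 10655 regions with a peak in both Osa-deGrad lists, 95.03% also had a peak in a control list, and of the 10441 regions in both control lists, 91.7% had a peak in an Osa-deGrad list. Libraries did not group by genotype on overlap of covered bases. The Jaccard index was 0.493 between the Osa-deGrad libraries and 0.454 between the controls, against 0.549 between the 2 replicate 2 libraries, 0.427 between the 2 replicate 1 libraries, and 0.465 and 0.436 for the crossed pairs.

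Peaks at osa itself, the gene whose GFP-tagged protein was targeted, were found in all 4 libraries. Across osa and 5 kb on either side (gene on 3R, 17687818 to 17718350, dm6), the Osa-deGrad libraries had 9 and 12 peaks and the controls 10 and 9. Of 17 regions there, 2 were deGrad-only, 1 was control-only and 4 were in all 4 lists, including 3R 17699147 to 17701867 with an authors' fold enrichment of 19.4 and 13.5 in Osa-deGrad and 16.1 and 17.7 in control wings. Accessibility of the gene does not measure the Osa protein, so these peaks do not check its degradation. At nub, the source of the driver, 5 of 15 regions were in all 4 lists and 1 was control-only (2L, 12582400 to 12582829). Across br, an ecdysone-induced transcription factor gene, and 5 kb on either side, 5 of 19 regions were in all 4 lists and 0 were specific to a genotype. At w, 2 of 5 regions were in all 4 lists and 0 were specific. Around the Hsp70 genes, Hsp70Aa, Hsp70Bb and Hsp70Bbb had 0 regions. Hsp70Ab had 2 regions and Hsp70Bc 1 in the 5 kb flanks, none of them specific to a genotype. In the flank of Hsp70Ba lay 1 deGrad-only region (3R, 12460118 to 12460493), at percentile ranks of 86.9 and 3.10. It lay outside Hsp70Ba (12465453 to 12467776), with its summit 14 bp from an end of another annotated gene. None of these regions overlapped an Hsp70 gene.

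The next comparison asked which regions were open in 1 genotype only. The lists held 862 control-only regions and 530 deGrad-only regions, or 5.45% and 3.352% of the regions in at least 2 lists. The 5 strongest control-only regions were assigned to vvl, Efa6, arr, CG10822 and al. The 5 strongest deGrad-only regions were assigned to CG12541, bs, VhaAC45, CG17059 and RanBPM. The genotype split, with 1392 specific regions, exceeded the crossed split, which held 801 (443 in Osa-deGrad 1 and control 2, 358 in Osa-deGrad 2 and control 1). It stayed below the split by replicate number, with 1816 regions, 1630 of them in the 2 longer lists. When all lists were cut to 13953 peaks, the genotype split held 1331 regions, the split by number 1275 and the crossed split 757. Among the alternative region calls on all 4 libraries, only this one put the genotype split above the split by number. With −log10 q minima of 5 and 10 the split by number held 2108 and 2182 regions, against 982 and 568 by genotype. Among regions that differed in both same-numbered pairs, the direction in replicate 1 went with the direction in replicate 2 (odds ratio 2.88, Fisher's exact test over regions, two-sided, p = 1.21e-32). By construction this test leaves out the 1816 regions of the split by number. It therefore sets the genotype split against the crossed split only and does not weigh genotype against replicate number. Most specific regions were weak peaks. The median percentile rank of their weaker peak was 18.8 for deGrad-only and 18.95 for control-only regions, and 30 deGrad-only and 65 control-only regions had both peaks above a rank of 50.

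The strongest control-only region lay on 3L at 6834199 to 6834588, 39523 bp from the nearest end of vvl, which encodes a POU-domain transcription factor. It ranked at 88.1 in control 1 and 95.002 in control 2, with the authors' fold enrichment at 9.21 and 11.1. Regions inside gene bodies followed at Efa6 (3R, 22593708 to 22594213) and at arr, the Wingless coreceptor gene (2R, 13465132 to 13465543, ranks 91.3 and 79.1). A region inside the homeobox gene al (2L, 381503 to 381742) ranked at 80.6 and 76.9, and another control-only region lay beside the gene at 388762 to 389075. At aos, which encodes a secreted inhibitor of the EGF receptor, the control-only region (3L, 16480076 to 16480544) ranked at 95.03 and 69.9. The others of the 12 strongest lay within for (2L, 3632077), Glut4EF (3R, 9911111), mamo (X, 13921043), twin (3R, 24213593), Ten-a (X, 12124541) and dpy (2L, 4583509), and 283 bp from CG10822 (2R, 19950631). By nearest gene end, the mamo, twin, Ten-a and dpy regions were assigned to CG11068, CG17786, CG2750 and HP6.

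Of the 12 strongest deGrad-only regions, 10 lay within 500 bp of a gene end. The first was on X at 7066038 to 7066224, 92 bp from CG12541, and ranked at 71.9 in Osa-deGrad 1 and 76.1 in Osa-deGrad 2. A region inside bs, the serum response factor gene of intervein cells, was next (2R, 24343487 to 24343804, ranks 67.4 and 68.1), 822 bp from the gene's end. Another region inside bs (2R, 24366614 to 24367067) was control-only, at ranks of 6.77 and 46.0. The region at VhaAC45, a vacuolar ATPase accessory gene, lay 13 bp from the gene's end, that at PheRS-m, a mitochondrial phenylalanyl-tRNA synthetase gene, 6 bp, and that at the mitochondrial ribosomal protein gene mRpS33 2 bp. Regions at CG17059, frtz, Tmem63, Pcif1, Fibp and Moca-cyp lay 3, 10, 60, 13, 194 and 297 bp from a gene end, and that at RanBPM 592 bp.

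**Figure D1:**
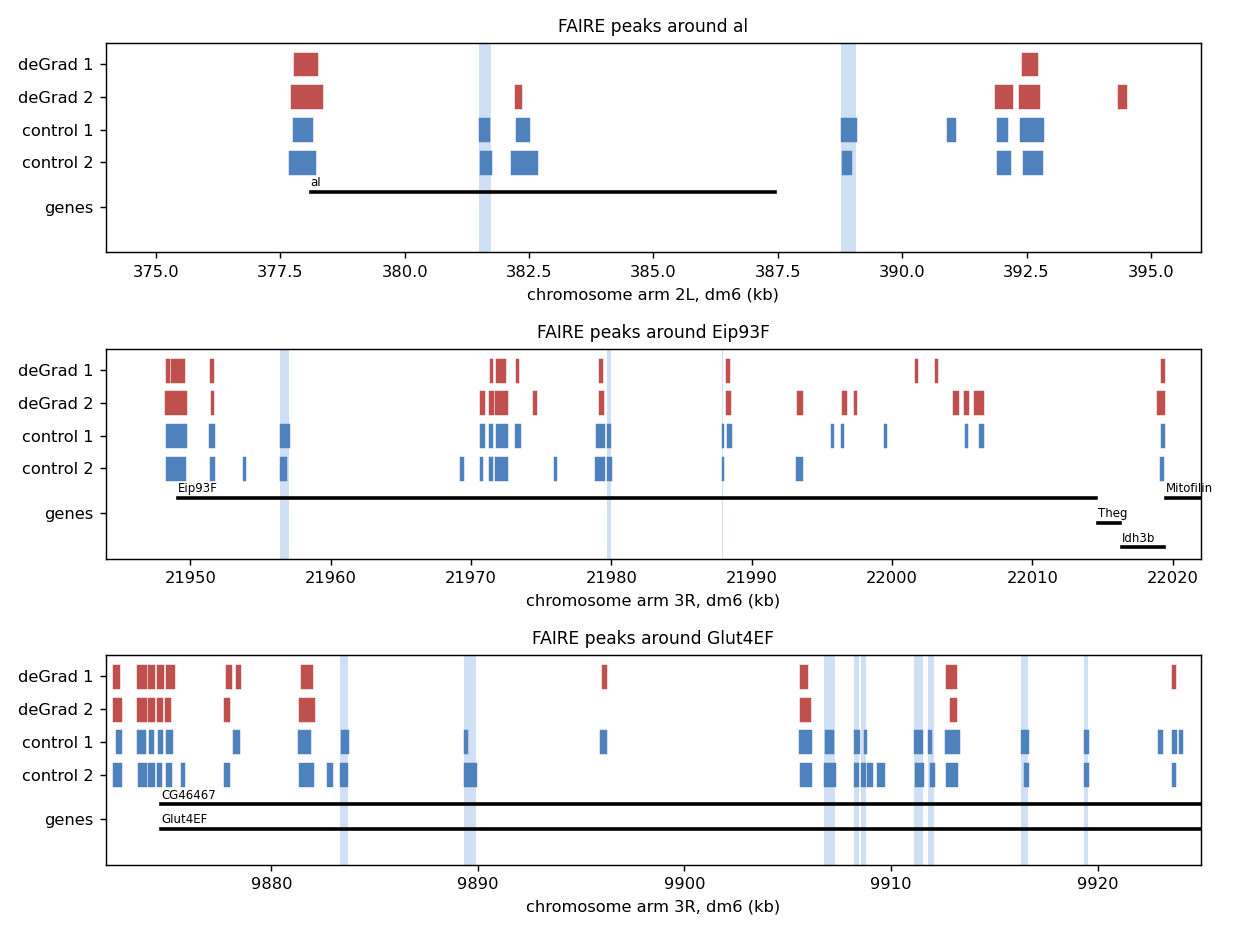
Positions of FAIRE peaks (x axis, kb on dm6; 1 line per library on the y axis) around al, Eip93F and Glut4EF, with Osa-deGrad peaks in red, control peaks in blue, protein-coding genes as black lines and control-only regions shaded. There are 2 control-only regions at al and 3 at Eip93F; around Glut4EF, from 9883342 to 9919555 on 3R, 9 of 14 regions are control-only.

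Where the specific regions lay was compared next. Control-only regions lay mostly away from gene ends and deGrad-only regions did not. Of 862 control-only regions, 136 (15.8%, 95% Wilson interval 13.5 to 18.4) had their summit within 500 bp of a gene end, against 278 of 530 deGrad-only regions (52.5%, 48.2 to 56.7) and 49.4% of the 7900 regions in all 4 lists. The median distance to a gene end was 3724 bp for control-only, 412 bp for deGrad-only and 520 bp for shared regions. Farther than 500 bp from gene ends, 535 control-only regions lay within gene bodies and 191 between genes, against 198 and 54 deGrad-only regions. The shares differed by 36.7 percentage points (odds ratio 5.89, Fisher's exact test over regions, two-sided, p = 2.54e-47, Benjamini-Hochberg adjusted over 11 location tests 3.99e-47). Control-only regions also differed from regions in all 4 lists (Fisher's exact test, p = 9.48e-87), whereas for deGrad-only regions the difference of 3.07 points did not pass (exact p = 0.178).

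The gap was present in both same-numbered pairs and differed in size between the crossed pairs. In replicate 1, 46.3% of regions with a peak in Osa-deGrad alone lay near a gene end, against 28.3% of those in the control alone. In replicate 2 the shares were 43.7% and 21.0%. They were 51.7% and 18.3% for Osa-deGrad 2 against control 1, but 36.9% and 34.3% for Osa-deGrad 1 against control 2. Without Osa-deGrad replicate 2 the gap was 1.497 points, where 1 list decided deGrad-only and 2 lists control-only regions. Libraries of the same genotype differed too, with 46.2% of regions in Osa-deGrad 2 but not Osa-deGrad 1 near a gene end against 27.3% in the reverse case, and 41.7% against 25.8% for control 2 and control 1. Regions in both replicate 2 lists alone and in both replicate 1 lists alone differed as well, at 55.1% and 24.7% (Fisher's exact test over regions, p = 2.20e-15), and the 2 sets of the crossed split at 43.3% and 25.5% (p = 1.27e-07). Over whole lists, 48.3% ± 1.92 (SD, n = 2) of Osa-deGrad peaks and 42.6% ± 2.01 (SD, n = 2) of control peaks lay near a gene end, and in lists of equal length 50.4% ± 4.79 and 44.4% ± 4.596.

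**Figure D2:**
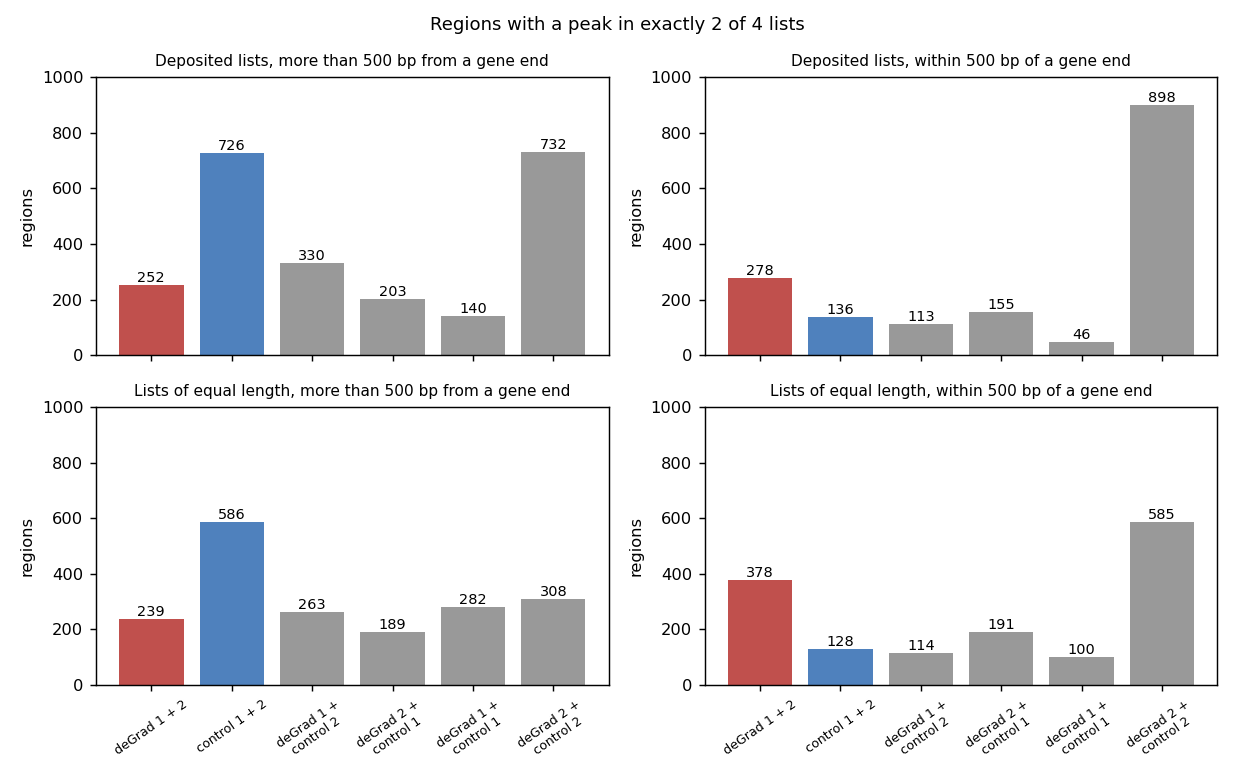
Number of regions (y axis) with a peak in exactly 2 of the 4 lists, by the pair of libraries that holds them (x axis), for deposited lists (top) and lists cut to 13953 peaks (bottom), more than 500 bp from a gene end (left) and within 500 bp (right). Red bars are deGrad-only, blue bars control-only and grey bars pairs that mix the genotypes, and away from gene ends control-only regions number 726 and 586 against 252 and 239 deGrad-only regions.

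**Figure D3:**
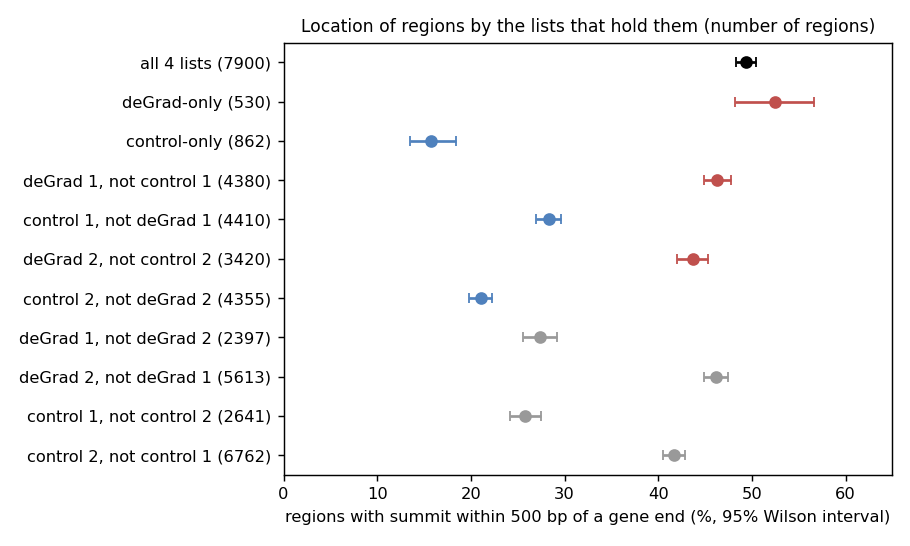
Share of regions with the summit within 500 bp of a gene end (x axis, percent, with 95% Wilson intervals that cover counting error only) for sets of regions named by the lists that hold them (y axis, number of regions in parentheses), with Osa-deGrad sets in red, control sets in blue, comparisons within a genotype in grey and shared regions in black. The control-only set is lowest, at 15.8%, and sets within a genotype lie between 25.8% and 46.2%.

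The chromosome carrying the driver and the width of regions were compared as well. Chromosome 2 held 38.1% of deGrad-only, 34.8% of control-only and 35.6% of shared regions, and the difference of 3.31 points between the specific sets did not pass the test (Fisher's exact test, two-sided, p = 0.227). It passed in opposite directions without Osa-deGrad replicate 2 (-3.09 points, exact p = 0.0344) and without control replicate 2 (4.25 points, exact p = 0.0013). DeGrad-only regions were narrower than control-only regions, with a median of 230 against 280.5 bp and a difference in mean log2 width of -0.28 (permutation test, two-sided, p = 1e-05, the smallest possible). This sign turned without control replicate 1 (0.37) and without control replicate 2 (0.62). In those settings 1 list decided control-only regions. Regions in 1 list were narrower (median 156 bp), so the sign can turn by construction.

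The gene lists asked whether known wing, hormone and cell type genes held more specific regions than other genes. None of the 13 lists passed for both directions together after adjustment. Regions were assigned to the gene with the nearest end, which can lie many kb away. Wing selector and patterning genes had 18 control-only and 5 deGrad-only regions out of 206 (odds ratio 1.33, adjusted exact p = 0.704), but 13 and 12 of 228 with assignment by gene body and 5 kb flanks. By nearest end the control-only ones were assigned to 11 genes, among them salr (2L, 11378856 to 11379571, 5551 bp away), salm (2L, 11415761 to 11415955, 18455 bp away), hth (3R, 10572041 to 10572560) and nub, and the deGrad-only ones included bs, Sox15, Awh and hth. Ecdysone response genes had 9 and 3 of 178 (odds ratio 0.78, adjusted exact p = 0.907), with control-only regions assigned to Eip93F (3R, 21979694 to 21980004), Eip74EF, ImpE1 and Eip75B and deGrad-only regions to EcR and crol. A deGrad-only region assigned to br by nearest gene end (X, 1562418 to 1562707) lay 12594 bp from br, within Mur2B. Signalling genes had 15 and 3 of 238 (0.87, adjusted exact p = 0.907), control-only for aos, fj, N and ds, deGrad-only for ds, fj and brk. Cuticle, hair and wing differentiation genes had 14 and 3 of 172 (1.17, adjusted exact p = 0.907), control-only for Cht6, ovo, m and shot, deGrad-only for Cpr64Ad, b and dpy. Sensory organ genes had 5 and 4 of 49 (2.44, adjusted exact p = 0.237), control-only for Sox102F, ac, chn and nvy, deGrad-only for shep, sv, chn and sc. SWI/SNF subunit genes had 1 and 2 of 23 (1.77, adjusted exact p = 0.907), control-only for osa and deGrad-only for BCL7-like and osa. The regions assigned to brk, sc and Cpr64Ad lay within CG1677, CG32816 and CG43367.

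Among markers of other cell types, tracheal genes had 10 control-only and 1 deGrad-only region of 56 (odds ratio 2.63, adjusted exact p = 0.187). The control-only regions were assigned to vvl, Cad99C, knrl and uif, and vvl and knrl also act in the wing itself. The 3 vvl regions lay 34033, 35480 and 39523 bp from the gene, with 0 control-only regions within 5 kb of it. Both directions together passed without Osa-deGrad replicate 2 (odds ratio 2.45, adjusted exact p = 0.00965). For control-only regions alone, a test chosen after seeing the data, the tracheal list passed (odds ratio 3.95, Fisher's exact test, adjusted p = 0.0103). It did not pass with assignment by gene body and 5 kb flanks (2.43, adjusted exact p = 0.396). By nearest end vvl, Cad99C and knrl held 3 control-only regions each. The test counts regions of the same gene as independent, so its p rests on few loci. Muscle markers had 2 control-only regions of 26, at how and Mef2 (1.06, adjusted exact p = 1), and hemocyte markers 1 of 14, assigned to crq but lying within ex (1.15, adjusted exact p = 1). Markers of neurons and glia had 0 specific regions of 14 (0.36, adjusted exact p = 0.907) and those of fat body 0 of 2 (2.07, adjusted exact p = 1). Transgene vector genes had 1 control-only region of 14, assigned to nub (1.15, adjusted exact p = 1), and with gene bodies and flanks 0 control-only and 1 deGrad-only of 17. Ribosomal protein genes had 4 deGrad-only regions of 89, at RpL13, RpL32, RpS3 and RpS10b, and 0 control-only regions (0.54, adjusted exact p = 0.704). With assignment by gene body and flanks this list passed (0.43, adjusted exact p = 0.0191), with 2 control-only and 9 deGrad-only regions of 285. In the tests of 1 direction, chosen after seeing the data, the control-only odds ratio was then 0.15 (adjusted exact p = 0.000395) and the deGrad-only one 0.99. By nearest gene end the control-only test did not pass (0.096, adjusted exact p = 0.101). The gene list tests were not matched on location. Among regions in at least 2 lists, control-only regions made up 1.80% near gene ends and 8.79% farther away. A low control-only rate in this list was therefore not separated from the gap near gene ends.

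**Figure D4:**
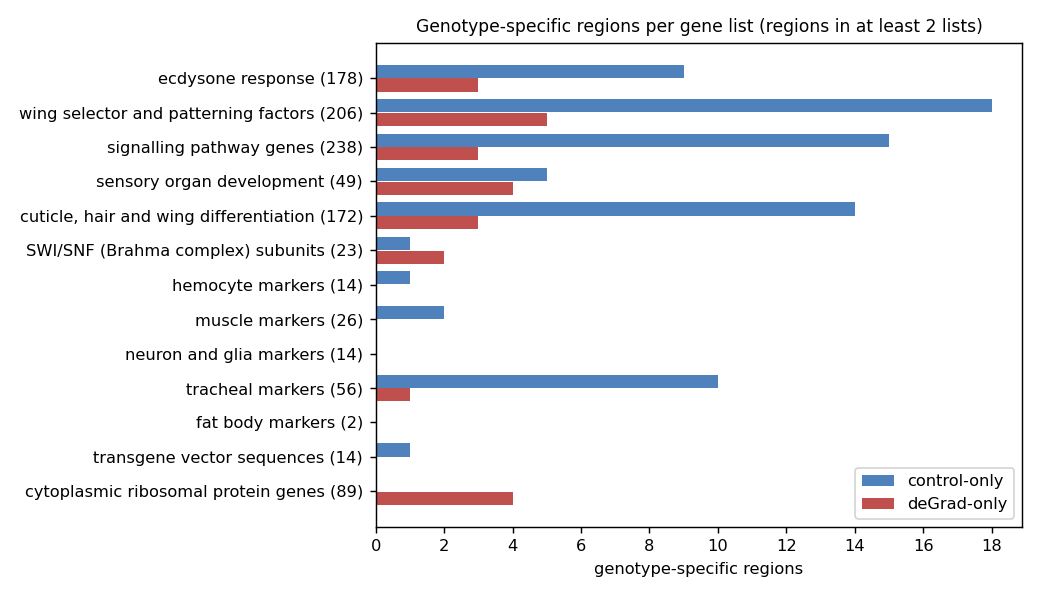
Number of control-only (blue) and deGrad-only (red) regions (x axis) for each gene list (y axis, with the number of its regions present in at least 2 lists in parentheses). Wing selector and patterning factors hold 18 control-only and 5 deGrad-only regions by nearest gene end, as drawn, but 13 and 12 with gene bodies and 5 kb flanks, and ribosomal protein genes hold 0 and 4 as drawn and 2 and 9 with flanks.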

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

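Tests of single directions in the gene lists were chosen after the result was seen; every alternative below was planned. Of 262 alternative values, 204 kept their direction and side of the threshold (or stayed within the allowed spread), 41 reversed, 13 moved, 3 gained and 1 lost a call. The gap near gene ends stayed past its threshold except without Osa-deGrad replicate 2, and ranged from 1.497 to 41.95 points when 1 library was left out. Most reversals were gene lists that passed no test. Some of their odds ratios lay near 1, but others did not, such as 0.142 for hemocyte markers and 4.19 for neurons and glia. The cause of the reversals and moves was not tested, except where stated.

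With a −log10 q minimum of 10, deGrad-only regions numbered 234 and control-only regions 334, the split ratio was 0.464, and the odds ratios were 1.0015 for ecdysone response, 0.374 for SWI/SNF and 0.494 for muscle genes. With a minimum of 5, the signalling list was at 1.10 and the difference in Jaccard index between same-genotype and other pairs at -0.00396, against 0.00468 for the deposited lists. Above a percentile rank of 50, which leaves fewer peaks by construction, there were 30 and 65 regions, with ecdysone response at 1.26, signalling at 1.66 and neurons and glia at 4.19. With lists of equal length, the chromosome 2 difference was -0.0059 points, hemocyte markers were at 0.382 and transgene genes at 0.988. With summits within 100 bp, ecdysone response was at 1.01, signalling at 1.23, hemocyte markers at 0.92, muscle at 0.92 and transgene genes at 0.752. With a 50% overlap, neurons and glia were at 1.18. With gene bodies and flanks, signalling was at 1.12, cuticle at 0.916, hemocyte markers at 0.142, neurons and glia at 1.44, transgene genes at 0.941 and ribosomal protein genes at 0.429. With a background of exactly 2 lists, signalling was at 1.14 and fat body at 0.376.

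Leaving out 1 library let 1 list decide a genotype, so counts grew by construction, to 806 to 2851 deGrad-only and 1190 to 3639 control-only regions. The chromosome 2 difference ranged from -3.09 points (without Osa-deGrad replicate 2, exact p = 0.0344) to 4.25 points (without control replicate 2, exact p = 0.0013), and the log2 width difference from -0.83 to 0.62. Odds ratios ranged from 0.883 to 1.41 for wing selector, 0.741 to 1.24 for signalling, 0.5999 to 1.77 for SWI/SNF, 0.621 to 1.04 for hemocyte, 0.818 to 2.44 for muscle, 0.674 to 1.74 for neuron and glia, 1.896 to 2.45 for tracheal, 0.659 to 2.60 for fat body, 0.847 to 2.28 for transgene and 0.564 to 1.07 for ribosomal protein genes. The tracheal list passed without Osa-deGrad replicate 2 (Fisher's exact test, adjusted p = 0.00965). The split ratio and the direction odds ratio have no value with a library left out, and the GC content and motif alternatives were not run.

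The labels do not say that a replicate number marks a shared batch, so the libraries were taken to share only a number. Presence differences between the replicates of each genotype correlated at 0.0572 over regions. This value leaves out any shift common to all regions, such as list length, so it cannot exclude a shared batch. The Jaccard index was highest between the replicate 2 libraries (0.549) and lowest between the replicate 1 libraries (0.427). As a replicate block, lists cut to equal length within each number gave 571 deGrad-only and 773 control-only regions. In the deposited lists the genotype split against the crossed split alone had a ratio of 1.74, against 1.06 over both other splits. With 3 splits no share under 0.05 can be reached. Depth was unknown, and the weak peaks that make up most specific regions depended on the threshold: with a −log10 q minimum of 5, 166 of the 530 deGrad-only and 307 of the 862 control-only regions kept their call, and with a minimum of 10, 5 and 29 did. The other regions called at those minima were different ones, so the gap near gene ends there is not that of the same set.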

Other observations

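The tests on list length, on shifts within a genotype, on the ranks of shared regions and on replicate numbers were chosen after the result was seen; those on regions off chromosome 2, chance placement and the Glut4EF interval were also added after the data were seen, but what they would show was written down before their results were known. The genes singled out here were chosen after their values were seen. Control-only regions recurred at single genes: 43 genes had at least 3, against 2 genes with at least 3 deGrad-only regions, gpp and Myo81F, and Myo81F also had 4 control-only regions. Glut4EF had 9 of its 17 regions control-only, CG3655 5 of 17, CG4374 5 of 12, mub 4 of 21, osp 4 of 15, ovo 4 of 12 and sbb 4 of 11. CG42747 (4 of 13), Tet (4 of 23) and hth (4 of 19) each also had 1 deGrad-only region. Although the labels give the pupae as female, 19 regions were called on the Y chromosome, 8 of them in all 4 lists and 0 specific to a genotype, with 9 to 14 Y peaks per library. Whether these are reads from repeats placed on the Y chromosome or from male tissue was not tested.

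Regions in all 4 lists were re-ranked among those 7900. Over all of them, both controls ranked above both Osa-deGrad libraries in 17.6% and below both in 18.0%, where chance gives 16.7%. By replicate number, replicate 1 ranked above in 18.2% and replicate 2 in 17.6%. Split by location, both controls ranked above both Osa-deGrad libraries in 23.5% of distal regions (more than 500 bp from a gene end) and 11.5% of regions near gene ends. The reverse held for 14.0% and 22.1%. A region assigned to trh by nearest end (3L, 385402 to 385802, 7089 bp away) ranked at 0.348 and 2.52 in Osa-deGrad and at 60.7 and 72.9 in control wings. Regions assigned to sn, lab, if and Ser, 3154, 3808, 13173 and 9055 bp away, also ranked lower in both Osa-deGrad libraries. Regions assigned to Arl8 and CG9588, 4806 and 5 bp away, ranked higher in both. Of regions assigned to Tsp, 1 (2L, 6693485 to 6693898, 6968 bp away) ranked lower and another (6705075 to 6705546, 3823 bp away) higher in both. The split by number was nearly as large among distal regions, with both replicate 1 libraries above both replicate 2 libraries in 21.7% and the reverse in 14.0%. Near gene ends these shares were 14.7% and 21.4%, more in sum than those by genotype.

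The position of control-only regions away from gene ends was weighed first. With lists of equal length the gap was 43.3 points, which argues against list length, and off chromosome 2 it was 33.4 points, which argues against a strain difference on the driver's chromosome. A shift between gene ends and distal regions also separated libraries of the same genotype, by at least 15.9 points, and regions specific to the replicate numbers lay near gene ends in 24.7% (replicate 1) and 55.1% (replicate 2), so such a difference between libraries could account for part or all of the gap. The gap was 1.497 points without Osa-deGrad replicate 2. There 1 list decided deGrad-only and 2 lists control-only regions, so the sets were not matched. This value alone therefore cannot show whether the gap depends on that library. Without Osa-deGrad replicate 1, where 1 list also decided deGrad-only regions, the gap was 25.9 points. Comparisons of 1 library against 1 gave 18.0 points in replicate 1 and 22.7 in replicate 2. They gave 33.4 points for Osa-deGrad 2 against control 1, but 2.62 for Osa-deGrad 1 against control 2. The size of the gap thus varied with the libraries compared. A loss of distal accessibility after Osa degradation stays open as an untested hypothesis.

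The ranks of distal regions in all 4 lists were weighed next. After ranking among distal regions alone, the differences between control and Osa-deGrad in replicate 1 and in replicate 2 correlated over regions at r = 0.200 (bootstrap SE 0.0156), which a uniform shift of all distal regions would not give. Start sites inside a gene count as distal here. A shift that acts differently on these and on other distal regions was therefore not excluded. The same correlation by replicate number was r = 0.141 (SE 0.0167). The 2 values do not compete, since an effect shared within a number cancels in the differences between genotypes, so this comparison decided nothing about replicate numbers. Regions are not independent replicates, and near gene ends the values were 0.0436 by genotype and 0.0789 by number.

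The recurrence of control-only regions at single genes was weighed last. Random placement among regions of the same location class gave a median of 19 genes with at least 3 (95% of placements 12 to 27) and as many as 43 in a share of 0.0001, the smallest that 10000 placements can give. For deGrad-only regions the share was 0.58. The placements were not matched on peak strength or on distance beyond 500 bp. Over 5 kb from a gene end lay 39.3% of control-only regions, against 17.7% of regions in all 4 lists. Placements were not run for the splits by number or crossed, so they cannot tie the recurrence to genotype. A loss of the Glut4EF interval from the Osa-deGrad strain could not be decided: between 9883342 and 9919555 on 3R, 2 regions had peaks in both Osa-deGrad lists, which argues against loss of the whole interval and leaves smaller losses open. A coordinated loss of accessibility at some loci is a hypothesis only, since neighbouring weak peaks may share a local background.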
